A study of Arabidopsis thaliana with 24 samples.

How the data were processed

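Transcript levels were measured by mRNA sequencing of Arabidopsis thaliana seedlings in 24 libraries, with 3 biological replicates in each of 8 groups, all assigned from the labels. Wild-type Col-0 seedlings had 4 treatments, which were mock (called KCl in some labels), 10 mM KNO3, 0.5 mM H2O2, and KNO3 with H2O2, and the mutants hbi-q and nlp7-1 each had mock and KNO3. Seedlings had grown for 7 days with 7 mM KNO3 and then for 2 days without nitrogen, and treatments lasted 3 h. Libraries were sequenced on a BGISEQ-500, per the labels' protocols. The labels give no batch or date beyond the replicate number.

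The files used here are 5 tables of the authors' differential expression results, 1 per comparison, and no values per library were analysed here. Per the series design text and the submitters' processing notes, the authors mapped reads with HISAT and Bowtie2 to TAIR10, counted reads per gene with htseq-count at its default parameters and fitted a generalized linear model with DESeq2. Versions of these tools are not given in the sources used here. Per the file headers, each gene has a base mean, which is the authors' mean signal of counts divided by size factors over the libraries of a fit. The log2 fold change and its standard error are on the log2 scale in the authors' deposited tables, per the file headers. The test score in the deposited tables equalled the log2 fold change divided by its standard error when checked. Each p-value in the deposited tables is from the authors' DESeq2 test, with a Benjamini-Hochberg adjusted p-value beside it, per the file headers. An adjusted p-value of 0 in a table is one below the smallest number the file format held.

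Which libraries entered each of the authors' fits is not given in the sources used here. The wild-type and hbi-q nitrate tables held the same base mean for all 22954 genes, as 1 joint fit would give, and the nlp7-1 table and the KNO3 with H2O2 table held other base means. Tables were normalized separately in that sense, so the comparisons set fold changes within a table against those of another and tested no levels across tables. The exceptions are levels of single groups, such as hbi-q and wild type in mock and after KNO3, derived from such tables, which enter only the additional observations. The base mean of NLP7 was also set across tables, without a test. The table of H2O2 against mock in wild type held 1810 genes, each with an adjusted p-value under 0.05 and at least a 2-fold change when checked, so a gene outside it is called not listed and is not called unchanged. Of these genes 1801 were also in the table of KNO3 with H2O2, and the 22311 genes in either table served as its background.

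The depth of each library is unknown. Base means summed to 2.01e+07 normalized counts per library for the wild-type and hbi-q tables, 2.09e+07 for nlp7-1 and 2.02e+07 for KNO3 with H2O2. For genes with a base mean over 100, the median standard error of the log2 fold change was 0.0960 in the wild-type and hbi-q tables alike, 0.180 in the nlp7-1 table, 0.0999 in the KNO3 with H2O2 table and 0.131 in the H2O2 table. The nlp7-1 comparison thus had the least precision. Whether the libraries keep strand is not given in the sources used here, so genes with an antisense partner are uncertain, as are near-identical copies such as NRT2.1 and NRT2.2, the CAB genes and the RBCS genes.

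Gene IDs were matched to the TAIR10.1 annotation for symbols and products only, and no coordinates were taken from it. All IDs of the nlp7-1 and H2O2 tables matched, while 39 IDs of the wild-type and hbi-q tables and 31 of the KNO3 with H2O2 table did not. Genes without a symbol there are given by locus ID. The nlp7-1 table also listed another set of genes, since 1164 genes of the wild-type table were not listed in it and 820 of its genes were not listed for wild type. Of these, 132 and 96 had a base mean over 100, against 1 and 1 between wild type and KNO3 with H2O2. Low counts alone therefore do not account for the other gene set, and its cause is not given in the sources used here.

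A gene was called in a pairwise comparison at an adjusted p-value under 0.05 and at least a 2-fold change, the criterion in the series design text. Pairwise values are the authors' own, and no count model was fitted here, since count tests planned before the data were examined need values per library. The difference between 2 nitrate responses was tested per gene as the difference of the 2 log2 fold changes divided by the root of the sum of their squared standard errors, two-sided against the normal distribution, with Benjamini-Hochberg adjustment and a call at an adjusted p-value under 0.05. This test took the 2 fold changes as independent, and by the labels they compare different libraries. The 3 differences were hbi-q against wild type over 22954 genes, nlp7-1 against wild type over 21790 genes, and wild type with H2O2 against without over 22204 genes. All 3 used the wild-type response, so they share its chance values. On simulated data with 50 changed genes per size, the test recovered 45, 33 and 49 genes at a true difference of 1 on the log2 scale in these 3 settings, and 23, 5 and 27 at 0.5. Among the unchanged genes 7, 4 and 9 were called. The changed genes had a wild-type base mean over 50, and noise was drawn at the deposited standard errors. Recovery would be lower where true errors are larger.

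The 19 gene lists tested were fixed before the data were examined. They cover nitrate uptake and reduction, ammonium assimilation and transport, reductant supply, nitrate regulators, HBI1 and related bHLH factors, antioxidant enzymes, NADPH oxidases, glutathione transferases, heat shock factors and proteins, oxidative stress signalling, jasmonate, salicylate and defence, cytokinin, phosphate starvation, iron, sulphur, shoot photosynthesis markers, root markers, and nuclear ribosomal proteins. The last was taken by the words of the product description and also holds some plastid ribosomal proteins. A planned list of organelle-encoded genes had no member in the tables. Each list's called members were set against all genes of the table with a hypergeometric test, one-sided for each direction and Benjamini-Hochberg adjusted over 190 tests, or over 114 tests for the differences. This test treats genes as independent, which members of a pathway are not. A set test with a correlation between genes needs values per library and was not run.

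Named genes followed a rule fixed before the data were examined. It took NLP7 and the HBI1 list, up to 3 called members per list with the largest change, the 3 highest and the 3 lowest called genes with a base mean of at least 50, and NIA1, NIR1, NRT2.1, LBD37, AT1G13300 and AT3G25790 in every nitrate comparison. Shoot and root markers are given as counts and medians. Overlaps of calls were set against the product of the list sizes divided by the genes tested in both, with a one-sided Fisher's exact test. Where 2 comparisons shared control libraries, 100 data sets with no true change were simulated from the standard errors.

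Alternatives were other fold limits of 1.5 and 4, no fold limit, an adjusted p-value under 0.01, leaving out the genes with the lowest base means, and, added after the data were examined, centring fold changes on their median, scaling the difference test by its robust SD, and picking responsive genes on a table outside the difference. The 5 planned comparisons of genotypes or of H2O2 at fixed nitrate had no table and were not run. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.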

Results

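Transcripts of Arabidopsis thaliana seedlings were profiled by mRNA sequencing in 24 libraries, 3 biological replicates in each of 8 groups. Wild-type Col-0 was sampled after mock treatment, 10 mM KNO3, 0.5 mM H2O2 or both, and the mutants hbi-q and nlp7-1 were sampled after mock treatment or KNO3. NLP7 is a transcription factor that controls the response to nitrate, and the HBI genes encode bHLH transcription factors. The labels do not say which HBI genes hbi-q lacks. Going by the series title, the comparisons ask how HBI factors and reactive oxygen species bear on nitrate signalling. Base means summed to between 2.01e+07 and 2.09e+07 normalized counts per library, and the depth of single libraries is unknown. Values are log2 fold changes ± standard error, adjusted p-values are Benjamini-Hochberg adjusted, and genes were called at an adjusted p-value under 0.05 with at least a 2-fold change.

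The mutated genes were looked at first. For NLP7, the authors' deposited table for nlp7-1 gave a base mean of 446, against 1057 in the table shared by wild type and hbi-q and 1324 in the table for KNO3 with H2O2. The ratio of the first to the second, relative to the median gene, was 0.432, and 167 of 17575 genes had a lower one. These tables were normalized separately, so this difference in level was not tested. Within nlp7-1, NLP7 was 1.15 ± 0.36 higher with KNO3 in the authors' deposited table (adjusted p = 0.00424), and the difference from the wild-type response of 0.28 ± 0.08 was 0.87 ± 0.36 (adjusted p = 0.0921). The wild-type and hbi-q groups share 1 base mean per gene, so HBI transcript levels in hbi-q could not be read.

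The first comparison asks which transcripts nitrate changed in wild type. Genes that take up and reduce nitrate rose together, and so did genes that supply reductant for it, that regulate nitrate responses or that make and sense cytokinin. In the authors' deposited table for wild type, NIR1 (nitrite reductase) rose 43.6-fold, NIA1 (nitrate reductase) 11.3-fold and the high-affinity transporter NRT2.1 9.96-fold, or 5.44 ± 0.05, 3.50 ± 0.07 and 3.32 ± 0.07 on the log2 scale, each with an adjusted p of 0. The bHLH gene HBI1 rose 39.5-fold (5.30 ± 0.16, adjusted p = 5.46e-226) in the authors' deposited table, and the LOB-domain regulator LBD37 42.5-fold (5.41 ± 0.11, adjusted p = 0). The myb-like factors AT1G13300 and AT3G25790 rose by 3.57 ± 0.12 and 5.64 ± 0.40 in the authors' deposited table. In total 2167 genes rose and 1264 fell among the 22954 listed.

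By list, 10 of 16 genes of nitrate uptake and reduction rose and 2 fell (adjusted p = 2.73e-06 for those that rose). The largest changes were those of NRT2.2 (7.85 ± 0.20), NIR1 (5.44 ± 0.05) and UPM1 (3.73 ± 0.07), a gene of siroheme synthesis, in the authors' deposited table. For reductant supply 7 of 8 rose (adjusted p = 4.4e-06), and the authors' deposited table listed the glucose 6-phosphate dehydrogenase G6PD3 at 5.02 ± 0.07, the ferredoxin-NADP reductase RFNR2 at 4.0 ± 0.06 and the 6-phosphogluconate dehydrogenase AT5G41670 at 3.96 ± 0.05. Ammonium assimilation and transport split, with 6 of 16 higher (adjusted p = 0.0126) and 4 lower (adjusted p = 0.0453). The asparagine synthetase ASN2 (3.66 ± 0.09) and the glutamate synthase GLT1 (3.26 ± 0.15) were among the first in the authors' deposited table. Among nitrate regulators 14 of 26 rose and 1 fell (adjusted p = 2.03e-07 for those that rose), with LBD39 at 6.92 ± 0.31 and LBD38 at 5.66 ± 0.13 in the authors' deposited table. Of 21 cytokinin genes 16 rose and 0 fell (adjusted p = 1.15e-11), led in the authors' deposited table by the isopentenyltransferase IPT3 (4.34 ± 0.13), the hydroxylase CYP735A2 (4.02 ± 0.11) and the response regulator ARR15 (3.62 ± 0.26). In the sulphur list 6 of 11 rose (adjusted p = 0.0014), including the sulphate transporters SULTR1;2 (3.39 ± 0.08) and SULTR1;1 (3.19 ± 0.18) in the authors' deposited table, and in the iron list 5 of 12 rose (adjusted p = 0.0159).

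Of the HBI1 list, 4 of 16 rose and 1 fell. HBI1 (5.30 ± 0.16), BEE2 (2.88 ± 0.16), BEE1 (2.63 ± 0.15) and AT5G50915 (2.09 ± 0.28) rose and CIB5 (-1.07 ± 0.14) fell in the authors' deposited table, while BEE3 stood at 0.51 ± 0.14 and IBH1 at -0.74 ± 0.10, both short of 2-fold. Oxidative stress signalling leaned down, with 8 of 32 lower (adjusted p = 0.00168) and 1 higher. The NAC factor ANAC032 fell 3.81-fold (-1.93 ± 0.11) in the authors' deposited table, the alternative oxidase AOX1D fell (-1.45 ± 0.26) and WRKY30 rose by 1.54 ± 0.26. Of 29 glutathione transferases 5 fell (adjusted p = 0.0783), among them GSTU4 (-2.17 ± 0.13) and GSTU24 (-1.74 ± 0.09) in the authors' deposited table. Antioxidant enzymes had 4 of 45 higher, with the monodehydroascorbate reductase MDAR6 at 3.16 ± 0.05 in the authors' deposited table. No NADPH oxidase of 8 was called in the authors' deposited table, with 0 higher and 0 lower. Called genes were few for heat shock (2 of 18 higher), jasmonate (2 of 19 higher and 1 lower), salicylate and defence (1 of 11 higher) and phosphate starvation (1 of 16 higher and 2 lower). The phosphate-starvation lipid gene MGD3 fell 7.37-fold (-2.88 ± 0.10) in the authors' deposited table.

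Nuclear ribosomal protein genes rose as a group, 141 of 309 with a median of 0.98 in the authors' deposited table (adjusted p = 2.11e-60). Shoot photosynthesis markers moved with them, since 12 of 20 rose, with a median of 1.04 in the authors' deposited table (adjusted p = 3.77e-07). Root markers had a median of 0.07, with 2 of 21 higher and 1 lower in the authors' deposited table. Genes at the extremes were AT4G15670 of the thioredoxin superfamily (10.02 ± 1.19), AT1G68238 (9.02 ± 0.84) and UMAMIT35 (8.64 ± 1.03), and at the low end the marneral synthase MRN1 (-5.80 ± 0.33), LCR85 (-5.46 ± 0.41) and AT5G36150 (-4.83 ± 0.43), per the authors' deposited table. Counts adjusted over the list alone were the same for all 19 lists except heat shock, which had 1 higher gene. Adjusted p-values of lists treat genes as independent, which pathway members are not.

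**Figure D1:**
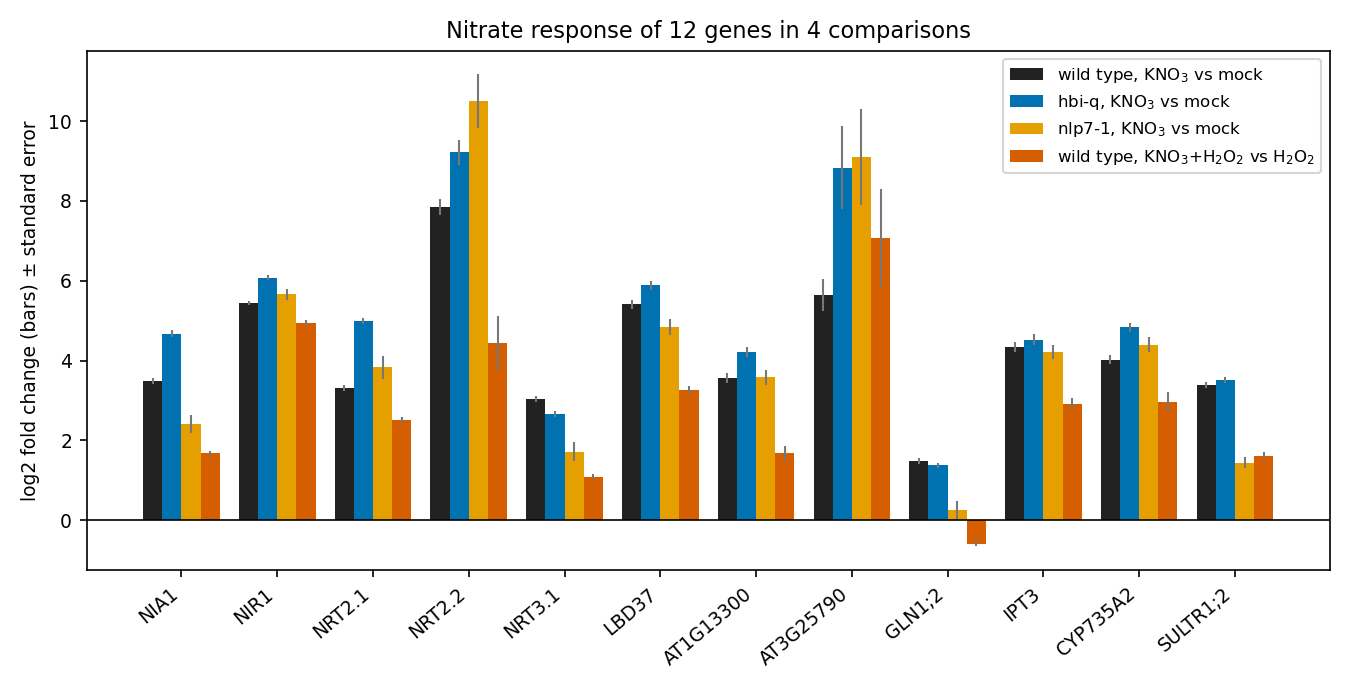
Bars are log2 fold changes of 12 genes and lines their standard errors, from the authors' deposited tables, for wild type, hbi-q and nlp7-1 (KNO3 against mock) and for wild type with H2O2 (KNO3 with H2O2 against H2O2). NIA1 stands at 3.50 ± 0.07, 4.68 ± 0.08, 2.42 ± 0.22 and 1.67 ± 0.07 in that order, and GLN1;2 lies below 0 with H2O2.

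The second comparison asks how hbi-q responded to nitrate. Genes of nitrate uptake and reduction, reductant supply, nitrate regulation and cytokinin rose as groups, and several nitrate genes rose further than in wild type, while some glutathione transferase and oxidative stress genes fell. In the authors' deposited table for hbi-q, NRT2.1 rose 31.7-fold (4.99 ± 0.07) and NIA1 25.6-fold (4.68 ± 0.08), each with an adjusted p of 0. In total 2313 genes rose and 1390 fell in that authors' deposited table. HBI1 rose by 4.17 ± 0.12 and BEE1 by 2.64 ± 0.15 in the authors' deposited table, BEE2 by 1.17 ± 0.36 and AT5G50915 by 2.46 ± 0.31. Lists rose and fell as 10 and 1 of 16 for nitrate uptake and reduction (adjusted p = 4.4e-06 for those that rose), 7 and 0 of 8 for reductant supply (6.59e-06), 14 and 0 of 26 for nitrate regulators (3.8e-07) and 17 and 0 of 21 for cytokinin (1.18e-12). Ammonium genes, with 5 of 16 higher (adjusted p = 0.0723), and iron genes, with 4 of 12 (0.0974), did not pass as groups. Of 29 glutathione transferases 10 fell and 1 rose (adjusted p = 3.38e-05 for those that fell), among them GSTU4 (-2.36 ± 0.13) and GSTU16 (-1.70 ± 0.11) in the authors' deposited table. In oxidative stress signalling 7 of 32 fell (adjusted p = 0.013), led by the NAC factor JUB1 (-2.83 ± 0.16) and WRKY75 (-1.95 ± 0.22) in the authors' deposited table. The systemic resistance gene FMO1 fell (-2.32 ± 0.10), 1 of 11 salicylate and defence genes (adjusted p = 1), and the NADPH oxidase genes AT1G19230 (-1.14 ± 0.11) and RBOHA (-1.01 ± 0.12) were the 2 of 8 that fell in the authors' deposited table. Shoot photosynthesis markers had 8 of 20 higher (adjusted p = 0.0025, median 0.86) and ribosomal protein genes 140 of 309 (3.39e-56, median 0.97) in the authors' deposited table, beside a root marker median of 0.16. The highest genes in the authors' deposited table were AT5G10210 (10.55 ± 1.18), AT3G46880 (10.46 ± 1.19) and AT1G68238 (10.28 ± 1.18), and the lowest were the seed storage genes CRU3 (-8.39 ± 2.45), SESA5 (-8.06 ± 2.43) and PAP85 (-7.01 ± 2.2), whose standard errors were large.

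The test of the difference itself asks where hbi-q and wild type responded unequally to nitrate. NRT2.1 responded more in hbi-q by 1.67 ± 0.10 (adjusted p = 4.99e-56), NIA1 by 1.18 ± 0.11 (4.55e-25), NRT2.2 by 1.37 ± 0.37 (0.00612) and NIR1 by 0.63 ± 0.08 (1.48e-13). The regulators BT2 (1.15 ± 0.25, adjusted p = 0.000288), BT1 (0.71 ± 0.21, 0.0202), AT1G13300 (0.65 ± 0.18, 0.0086) and LBD37 (0.48 ± 0.15, 0.0337) did too, and AT3G25790 missed the threshold at 3.19 ± 1.1 (0.0615). Responses were smaller in hbi-q for HBI1 (-1.14 ± 0.21, adjusted p = 3.96e-06) and BEE2 (-1.71 ± 0.39, 0.000694). The labels do not say which HBI genes are mutated, so an effect of a mutation on its own transcript cannot be told apart here. Differences were also below 0 for the ammonium transporters AMT1;3 (-0.73 ± 0.12, 1.49e-07), AMT1;5 (-0.80 ± 0.25, 0.0349) and AMT1;2 (-0.61 ± 0.11, 5.7e-06). The same held for JUB1 (-1.64 ± 0.24, adjusted p = 1.48e-09), GSTU10 (-1.31 ± 0.15, 1.01e-15), GSTU22 (-1.2 ± 0.16, 7.17e-12), FMO1 (-1.49 ± 0.14, 2.45e-25) and the pathogenesis-related gene PR2 (-1.35 ± 0.28, 0.00013). JUB1 and FMO1 fell with nitrate in hbi-q, so for them a difference below 0 is a deeper fall. Lowest of all were CYP82C2 (-5.27 ± 1.22), AT1G26390 (-5.10 ± 0.33) and AT1G26410 (-5.03 ± 0.39), the last 2 of the berberine-bridge-like oxidase family, and highest were LCR85 (2.90 ± 0.47), CLE2 (2.85 ± 0.95, adjusted p = 0.0486) and MRN1 (2.58 ± 0.36). Of 22954 genes 1288 differed, 488 above and 800 below 0. The count was 785 at an adjusted p-value under 0.01, 273 with at least 2-fold and 465 with the test scaled by its robust SD, a setting added after the data were examined. Named genes outside those 465 included NRT2.2, BT1, AT1G13300, LBD37, AMT1;5, CYP82C2 and CLE2.

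By list, the response differed upward in hbi-q for 5 of 16 nitrate uptake and reduction genes (adjusted p = 0.000145) and downward for 3. It differed upward for 4 of 26 nitrate regulators (0.0119) and 6 of 32 oxidative stress genes (0.000413), of which 2 others differed downward. The oxidative stress list had a median response of -0.48 in wild type and -0.23 in hbi-q. In hbi-q 7 of its 32 genes fell and 1 rose, so an upward difference there can be a weaker fall. Downward differences were found in 8 of 29 glutathione transferases (adjusted p = 5.96e-05), 5 of 11 salicylate and defence genes (0.000173) and 5 of 16 ammonium genes (0.00102). Adjusted over the list alone, the first 3 lists had 8, 8 and 7 higher members and the last 3 had 10, 9 and 5 lower ones. With at least 2-fold, nitrate uptake (adjusted p = 0.000235) and defence (0.0437) passed and the other 4 did not, and with robust scaling nitrate regulators (0.643) and oxidative stress (0.103) did not. Among the 2167 genes that rose in wild type, the response of 143 was weaker and of 62 stronger in hbi-q, but picking genes on wild-type calls favours weaker ones. With the 1977 genes that rose in nlp7-1 in their place, chosen after the data were examined, 56 were weaker and 107 stronger, so the direction turned, and for genes that fell the counts went from 106 weaker and 47 stronger to 48 and 157. This choice is not neutral either, since the nlp7-1 response correlated more with hbi-q (r = 0.864) than with wild type (0.801). It may favour stronger responses in hbi-q, so the direction stays unsettled.

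The third comparison asks how nlp7-1 responded to nitrate. Nitrate reduction and nitrite reduction genes rose in this mutant too, as did reductant supply, cytokinin and nitrate regulator genes, while ribosomal protein and shoot photosynthesis genes did not pass the test as groups. In the authors' deposited table for nlp7-1, NIR1 rose by 5.66 ± 0.14, NRT2.1 by 3.83 ± 0.28, NIA1 by 2.42 ± 0.22 (adjusted p = 2.64e-25) and LBD37 by 4.84 ± 0.19. NRT2.2 (10.51 ± 0.67), AT1G68238 (9.11 ± 1.2) and AT3G25790 (9.11 ± 1.2) rose the most and the anthocyanin regulator MYB90 (-4.62 ± 0.16) was among the 3 lowest with AT5G16740 (-5.82 ± 0.57) and AT2G40250 (-5.03 ± 0.50) in the authors' deposited table. HBI1 (5.46 ± 0.26), AT5G50915 (4.12 ± 0.30), BEE2 (2.96 ± 0.34) and BEE1 (2.56 ± 0.20) rose in the authors' deposited table. In total 2042 genes rose and 1499 fell of 22610 in the authors' deposited table. Lists rose in 9 of 16 genes for nitrate uptake and reduction (adjusted p = 2.06e-05), 7 of 8 for reductant supply (3.58e-06), 14 of 26 for nitrate regulators (1.24e-07), 15 of 21 for cytokinin (1.31e-10) and 6 of 11 for sulphur (0.00113). Of 18 jasmonate genes 7 rose (adjusted p = 0.00352), with the synthesis genes LOX2 (2.52 ± 0.18) and AOC2 (2.51 ± 0.28) in the authors' deposited table. Phosphate starvation genes fell in 5 of 16 (adjusted p = 0.0146) and oxidative stress genes in 8 of 31 (0.00396), with AOX1D at -2.09 ± 0.36 and AOX1A at -1.53 ± 0.12 in the authors' deposited table. Of 299 ribosomal protein genes 34 were called higher (adjusted p = 0.295, median 0.37) in the authors' deposited table, beside 2 of 20 shoot photosynthesis markers (adjusted p = 1, median 0.07) and 1 of 21 root markers (median 0.14).

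Tested directly, the nitrate response of NIA1 was lower in nlp7-1 than in wild type by -1.08 ± 0.24 (adjusted p = 0.000336). NRT3.1, the partner protein of NRT2 transporters, differed by -1.33 ± 0.25 (1.29e-05), ASN2 by -1.67 ± 0.22 (8.42e-12), the glutamine synthetase GLN1;2 by -1.23 ± 0.24 (3.54e-05) and RFNR1 by -1.26 ± 0.12 (8.66e-21). BT1 (-2.00 ± 0.29, adjusted p = 1e-09), NAC4 (-1.51 ± 0.28, 1.29e-05) and SULTR1;2 (-1.94 ± 0.17, 5.89e-28) were lower as well. For NIR1 the difference was 0.22 ± 0.15 (adjusted p = 0.33), for NRT2.1 0.51 ± 0.29 (0.235), for LBD37 -0.57 ± 0.22 (0.0664), for HBI1 0.15 ± 0.31 (0.786) and for AT1G13300 0.01 ± 0.22 (0.978), none past the threshold. Responses were higher in nlp7-1 for NRT2.2 (2.66 ± 0.70, adjusted p = 0.00442), NRT2.4 (1.77 ± 0.32, 6.23e-06), AT5G50915 (2.03 ± 0.41, 8.36e-05), CGA1 (1.06 ± 0.25, 0.00131) and the jasmonate repressors JAZ5 (1.64 ± 0.33, 8.46e-05) and JAZ10 (1.44 ± 0.33, 0.000597). The extremes were AT5G65980 (-4.38 ± 0.29), AT1G26390 (-4.19 ± 0.53) and AT1G26410 (-3.59 ± 0.45) at the low end, and LCR85 (5.04 ± 0.49), MRN1 (3.42 ± 0.37) and AT3G02620 (2.96 ± 0.20) at the high end. Of 21790 genes 2552 differed, 944 above and 1608 below 0. That count depended strongly on the test, with 972 at an adjusted p-value under 0.01, 790 with at least 2-fold and 72 with the test scaled by its robust SD, a setting added after the data were examined. Among the named genes outside those 72 were NIA1, NRT3.1, GLN1;2, NAC4, NRT2.2, NRT2.4, AT5G50915, CGA1, JAZ5 and JAZ10. The tables were normalized separately, so ratios within each table were set against each other. The nlp7-1 results also listed another set of genes, so a difference in processing cannot be told apart from an effect of genotype.

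By list, 118 of 298 ribosomal protein genes responded less in nlp7-1 (adjusted p = 5.36e-54, median difference -0.54), and so did 12 of 20 shoot photosynthesis markers (4.12e-08, median -0.89), while 2 of 21 root markers were lower and 0 higher. Lower responses were also found in 8 of 16 ammonium genes (6.74e-05) and 6 of 16 nitrate uptake and reduction genes (0.00403), of which 2 others were higher. Jasmonate genes had a higher response in 6 of 18 (adjusted p = 0.000517), with a list median of -0.15 in wild type and 0.70 in nlp7-1. Counts adjusted over the list alone were 176 for ribosomal proteins, 15 for shoot markers, 8 for ammonium, 6 for nitrate uptake and reduction, and 8 for jasmonate. With at least 2-fold, shoot markers (adjusted p = 2.02e-06) and ammonium (0.000203) passed, while ribosomal proteins (0.0983), nitrate uptake (0.190) and jasmonate (0.190) did not. With robust scaling none of these 5 lists passed, with 1 ammonium gene (0.179) and 0 members of the other 4 differing. Of 2112 genes that rose in wild type, 400 responded less and 50 more in nlp7-1, and of 1240 that fell, 218 less and 29 more. With genes called in hbi-q in their place, chosen after the data were examined, 299 of 2256 rose less and 84 more, and of 1360 that fell 136 fell less and 125 more, so for falling genes the balance was nearly lost. The hbi-q response correlated more with wild type (r = 0.931) than with nlp7-1 (0.864), so this choice may still favour weaker responses.

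**Figure D2:**
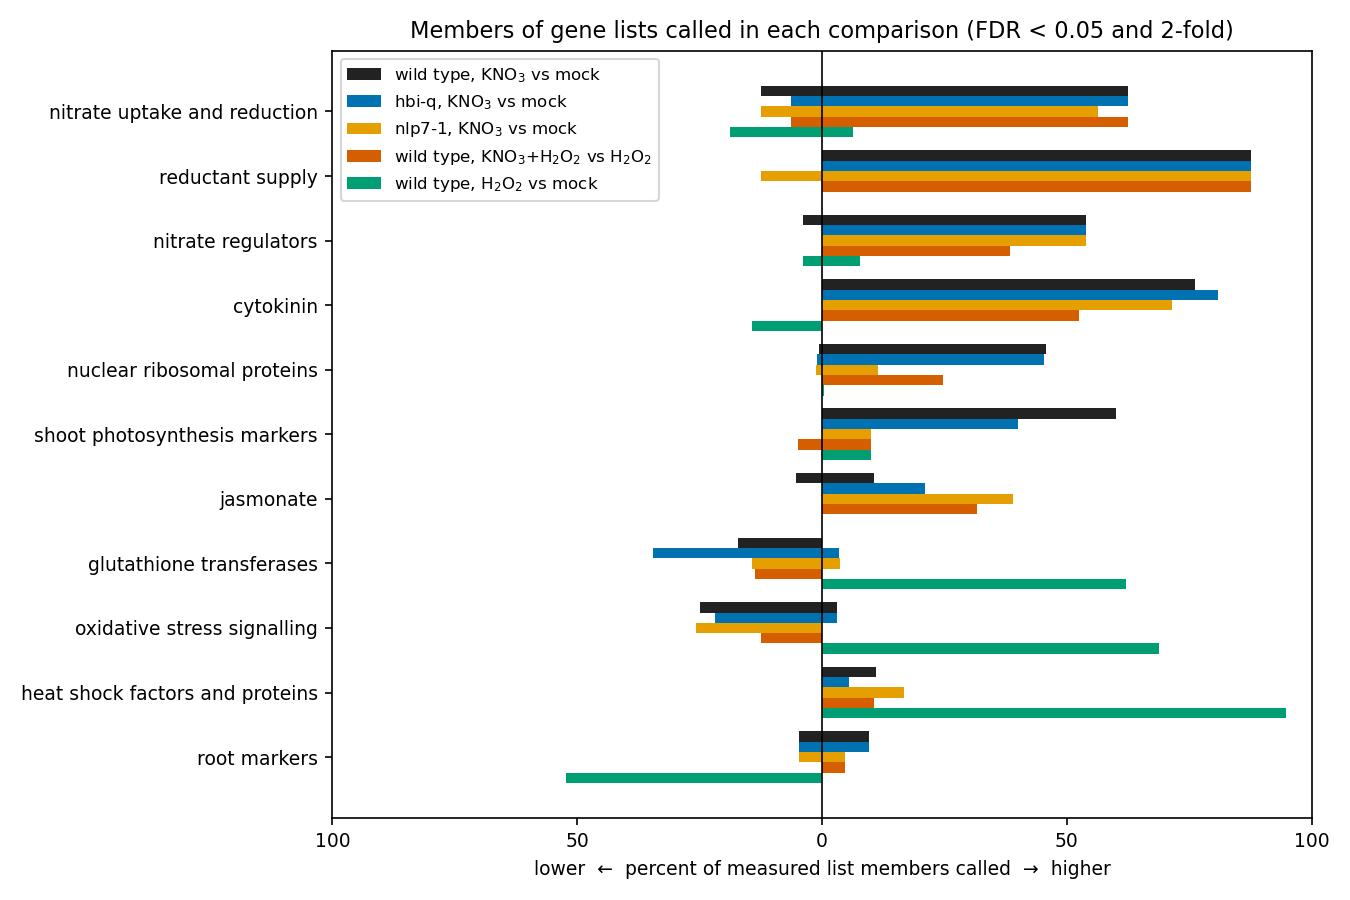
Bars give, for 11 gene lists on the vertical axis, the percent of measured members called higher (to the right) or lower (to the left) in the 5 comparisons. Reductant supply reaches 7 of 8 members higher in all 4 nitrate comparisons, and heat shock 18 of 19 with H2O2.

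The fourth comparison asks what H2O2 alone changed in wild type. Heat shock, glutathione transferase and oxidative stress genes rose together, defence and sulphur genes rose, and root markers fell. In the authors' deposited table for H2O2, the small heat shock proteins HSP23.6-MITO (10.12 ± 0.84), HSP17.6A (9.95 ± 0.38) and HSP17.6II (9.60 ± 0.37) rose the most, and 18 of 19 heat shock genes rose (adjusted p = 2.72e-21). Of 29 glutathione transferases 18 rose (adjusted p = 2.05e-15), including GSTU12 (5.51 ± 0.20) and GSTU25, 16.2-fold higher (4.01 ± 0.10), in the authors' deposited table. Of 32 oxidative stress genes 22 rose (adjusted p = 2.77e-20), including the kinase OXI1 (4.24 ± 0.15), ERF6 (3.69 ± 0.24) and the zinc finger factor ZAT12, 12.1-fold higher (3.60 ± 0.13), in the authors' deposited table. The camalexin synthesis gene PAD3 (2.96 ± 0.09) and PR1 (2.47 ± 0.15) were among 5 of 11 salicylate and defence genes that rose in the authors' deposited table (adjusted p = 0.00077), and BGLU28 (6.26 ± 0.40) and LSU1 (2.48 ± 0.13) among 5 of 11 sulphur genes (0.00077). Antioxidant enzymes had 2 of 46 listed as higher and NADPH oxidases 2 of 8 as lower, AT4G25090 (-1.16 ± 0.12) and RBOHB (-1.08 ± 0.16), in the authors' deposited table. Of 16 nitrate uptake and reduction genes 3 fell (adjusted p = 0.0557), which were NRT2.4 (-2.39 ± 0.18), NRT2.2 (-1.98 ± 0.61) and NRT2.1, 3.32-fold lower (-1.73 ± 0.09), and NRT2.5 rose (1.05 ± 0.10) in the authors' deposited table. Of 21 cytokinin genes 3 fell (adjusted p = 0.0974), among them CYP735A2 (-2.23 ± 0.27) and ARR6 (-1.52 ± 0.19), and of 16 ammonium genes 2 fell, among them AMT1;3 (-1.34 ± 0.10), and 2 rose in the authors' deposited table. Root markers fell in 11 of 21 (adjusted p = 1.31e-10), beside 2 of 20 shoot photosynthesis markers listed as higher. The lowest genes in the authors' deposited table were AT3G45700 (-4.77 ± 0.34) of the major facilitator family, XTH21 (-4.21 ± 0.23) of cell wall remodelling and AT1G19900 (-3.71 ± 0.29). The table lists 1112 higher and 698 lower genes and no others, so a gene not listed may have changed by less than 2-fold or not have passed the test.

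**Figure D3:**
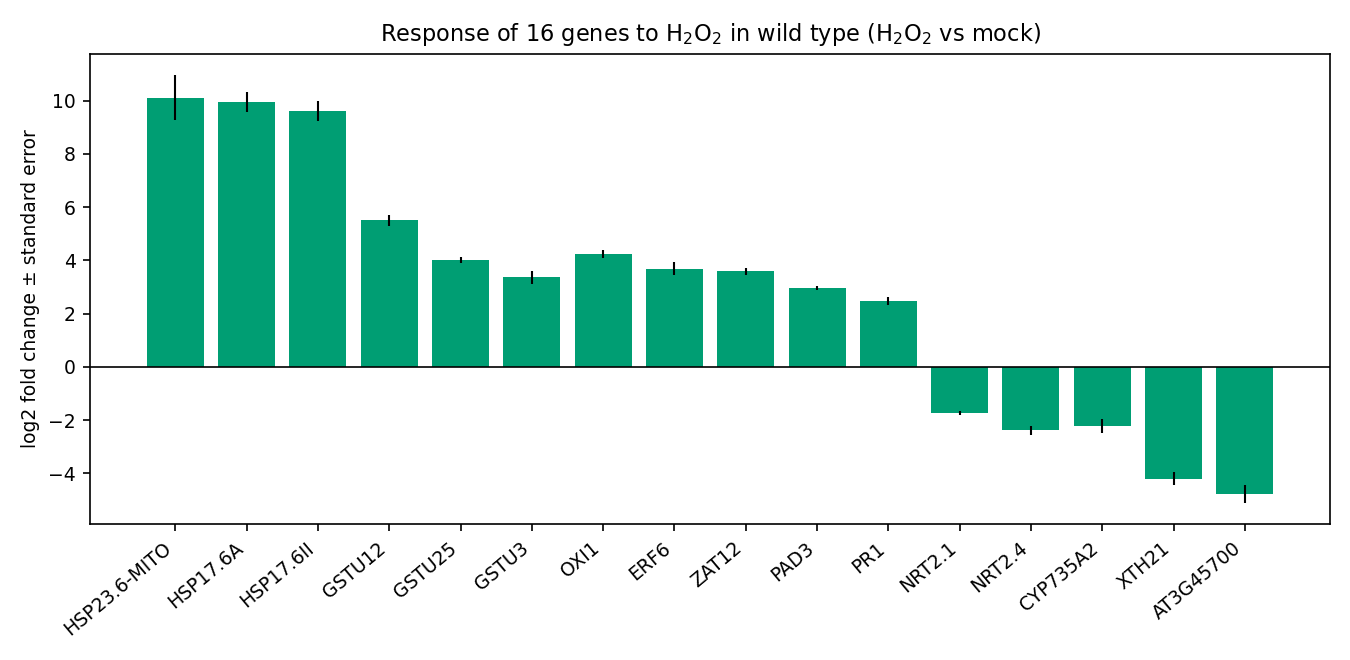
Bars are log2 fold changes of 16 genes with H2O2 against mock in wild type, and lines their standard errors, from the authors' deposited table. HSP23.6-MITO stands highest at 10.12 ± 0.84 and AT3G45700 lowest at -4.77 ± 0.34.

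The fifth comparison asks what nitrate changed in wild type when H2O2 was given with it, against H2O2 alone. Nitrate uptake and reduction, reductant supply and cytokinin genes still rose, with smaller changes for several. In the authors' deposited table for this comparison, NIR1 rose by 4.95 ± 0.06, NRT2.1 by 2.52 ± 0.08, LBD37 by 3.26 ± 0.10, NIA1 by 1.67 ± 0.07 and AT1G13300 by 1.67 ± 0.20. In total 1458 genes rose and 924 fell of 22302 in the authors' deposited table. The highest were AT1G68238 (7.45 ± 0.74), MBD3 (6.68 ± 0.86) and LBD39 (5.86 ± 0.36), and the lowest AT2G25625 (-4.15 ± 0.16), AT5G39520 (-4.11 ± 0.14) and AT5G35525 (-3.98 ± 0.25), per the authors' deposited table. Of the HBI1 list BEE1 (1.2 ± 0.18), BEE2 (1.65 ± 0.16) and AT5G50915 (1.85 ± 0.34) rose in the authors' deposited table, and HBI1 was not listed in it. Lists rose in 10 of 16 nitrate uptake and reduction genes (adjusted p = 1.24e-07), 7 of 8 for reductant supply (4.25e-07), 10 of 26 nitrate regulators (2.21e-05), 11 of 21 cytokinin genes (2.34e-07) and 5 of 11 sulphur genes (0.00233). Jasmonate genes rose in 6 of 19 (adjusted p = 0.00528), led by LOX2 (2.63 ± 0.09) and VSP1 (1.83 ± 0.30) in the authors' deposited table. Adjusted over the list alone, 8 jasmonate genes rose. PR1 fell (-1.75 ± 0.14), as did JUB1 (-2.11 ± 0.16) and the glutathione transferases GSTU16 (-1.50 ± 0.10), GSTU4 (-1.45 ± 0.10) and GSTU10 (-1.23 ± 0.09) in the authors' deposited table. Ribosomal protein genes rose in 76 of 308 (adjusted p = 1.04e-22, median 0.76) in the authors' deposited table, beside 2 of 20 shoot photosynthesis markers (adjusted p = 0.89, median -0.11) and 1 root marker of 21 (median 0.24).

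Tested directly, the nitrate response was smaller with H2O2 than without it for all sentinel genes but AT3G25790. LBD37 differed by -2.15 ± 0.14 (adjusted p = 1.85e-47), AT1G13300 by -1.89 ± 0.23 (2.71e-14), NIA1 by -1.83 ± 0.10 (1.49e-72), NRT2.1 by -0.80 ± 0.11 (1.74e-12) and NIR1 by -0.49 ± 0.08 (5.75e-08), and AT3G25790 by 1.43 ± 1.29 (0.468). Lower responses were also found for NRT2.2 (-3.41 ± 0.71, adjusted p = 2.04e-05), NRT3.1 (-1.95 ± 0.09, 6.09e-94), GLN1;2 (-2.08 ± 0.10, 1.09e-99), BT1 (-2.99 ± 0.23, 3.61e-35) and LBD38 (-2.28 ± 0.18, 1.06e-35). BEE1 (-1.43 ± 0.23, adjusted p = 2.32e-08), BEE2 (-1.23 ± 0.22, 7.16e-07), ARR15 (-2.04 ± 0.54, 0.00125), IPT5 (-1.79 ± 0.22, 1.6e-14), PR1 (-2.54 ± 0.37, 2.09e-10) and the iron uptake regulator FRU (-1.75 ± 0.19, 2.34e-18) were lower as well. NRT2.4 went the other way, with a response of -1.12 ± 0.13 without and 1.82 ± 0.18 with H2O2 in the authors' deposited tables, a difference of 2.94 ± 0.22 (adjusted p = 6.13e-37). H2O2 alone had lowered NRT2.4, so these 2 responses started from different levels. The lowest differences were AT1G26390 (-6.67 ± 0.37), AT3G60270 (-5.26 ± 0.29) and AT3G03670 (-4.98 ± 0.22), and the highest MRN1 (8.06 ± 0.39), LCR85 (8.01 ± 0.50) and AT1G14960 (5.16 ± 0.18). Of 22204 genes 5509 differed, 2534 above and 2975 below 0. With at least 2-fold 1206 did, and 644 with the test scaled by its robust SD, a setting added after the data were examined. These tables too were normalized separately, and the test set their within-table ratios against each other.

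By list, the response was lower with H2O2 for 20 of 20 shoot photosynthesis markers (adjusted p = 1.87e-16, median difference -1.09) and 82 of 307 ribosomal protein genes (1.17e-08, median -0.18), while of 21 root markers 4 were higher and 2 lower (median 0.37). It was lower for 16 of 26 nitrate regulators (2.76e-07), 13 of 21 cytokinin genes (5.05e-06), 19 of 45 antioxidant enzymes (2.59e-05), 7 of 8 reductant supply genes (6.2e-05), and 9 of 16 nitrate uptake (0.00046) and 9 of 16 ammonium genes (0.00046). Jasmonate genes had a higher response in 14 of 19 (adjusted p = 1.17e-08), among them VSP1 (1.57 ± 0.42), JAZ10 (1.51 ± 0.29) and JAZ5 (1.34 ± 0.26). The median response of that list was -0.24 without and 0.81 with H2O2, so its sign turned. Glutathione transferases went both ways, with 9 of 29 lower (adjusted p = 0.0525) and 6 higher (0.334), and with at least 2-fold those higher passed (0.0267), with robust scaling those lower (0.0238). Adjusted over the list alone, the counts were 20 shoot markers, 90 ribosomal protein, 17 regulator, 14 cytokinin, 20 antioxidant, 7 reductant, 9 nitrate uptake and 9 ammonium genes lower, and 14 jasmonate genes higher. With at least 2-fold, antioxidant, reductant and ribosomal protein genes no longer passed (adjusted p = 1 for each), and with robust scaling antioxidant (1), ribosomal protein (1) and jasmonate genes (0.103) did not. Of 2130 genes that nitrate raised without H2O2, 909 responded less and 43 more with it, and of 1261 lowered genes 632 less and 18 more. With genes called in hbi-q in their place, chosen after the data were examined, 734 of 2269 rose less and 94 more, and 493 of 1380 fell less and 144 more. The hbi-q response correlated more with nitrate without H2O2 (r = 0.931) than with it (0.853), so this choice may still favour weaker responses.

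**Figure D4:**
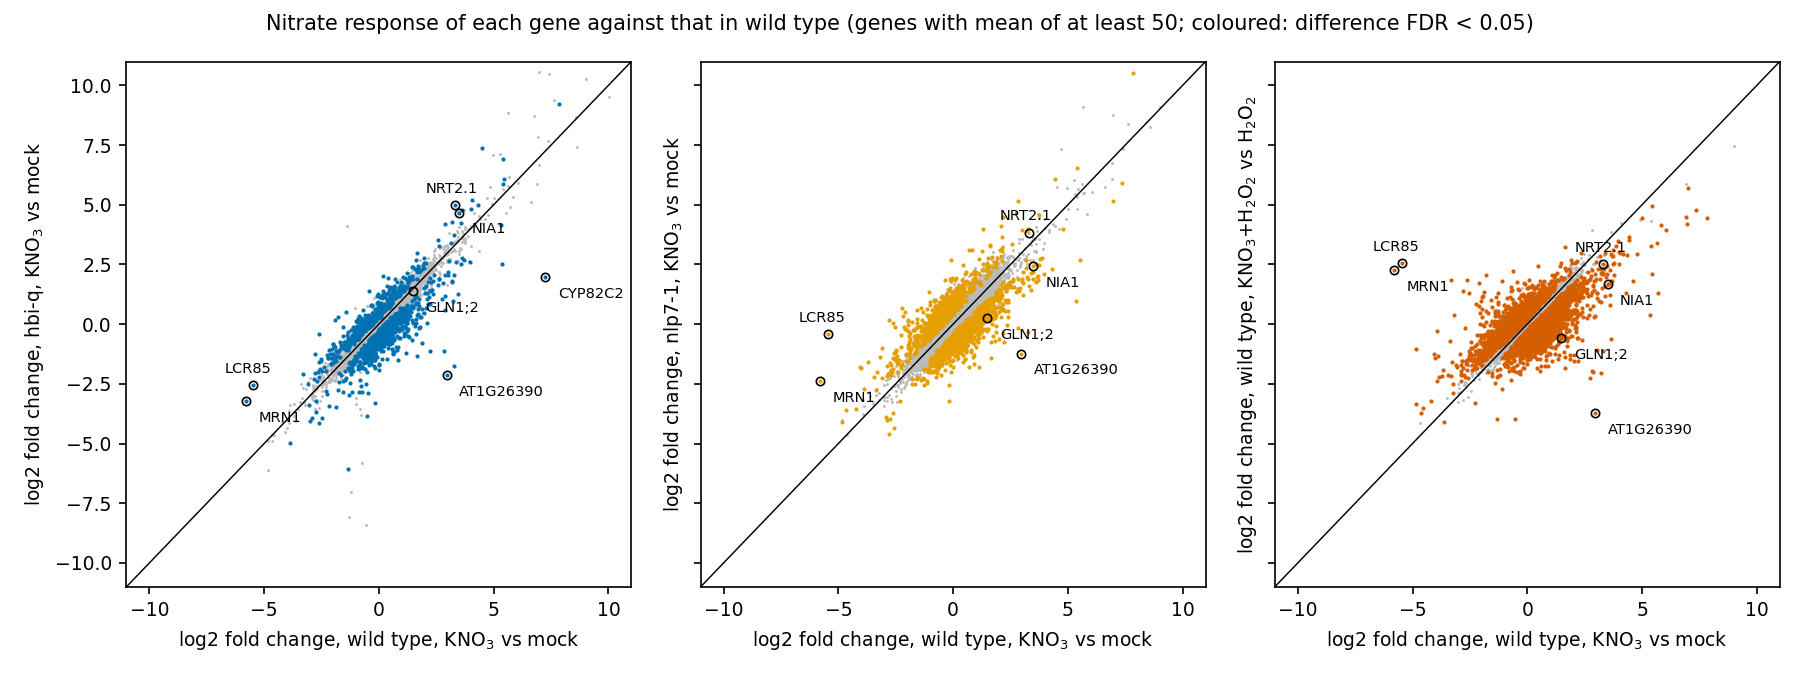
Each point is a gene with a base mean of at least 50, its log2 fold change with nitrate in wild type on the horizontal axis and in hbi-q, nlp7-1 or wild type with H2O2 on the vertical axis. Coloured genes differed at an adjusted p-value under 0.05, grey ones did not, the line marks equal responses, and MRN1 and LCR85 lie above it in all 3 panels.

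Calls were then compared between comparisons. Wild type and hbi-q shared 1768 genes that rose, against 218 from independent lists of these sizes, and 885 that fell, against 76.5. The corresponding counts for wild type and nlp7-1 were 1259 against 192 and 719 against 82.5, and for nitrate without and with H2O2 1067 against 140 and 491 against 52.4. Over a subset of 17253 genes the nitrate responses correlated across genes with r = 0.931 between wild type and hbi-q, 0.801 between wild type and nlp7-1, and 0.770 between wild type without and with H2O2, with 0.864 between hbi-q and nlp7-1, 0.853 between hbi-q and wild type with H2O2, and 0.784 between nlp7-1 and wild type with H2O2, and genes are not independent replicates. Over all genes listed for both members of a pair, 21520 to 22954, r was lower. It was 0.793, 0.731, 0.643, 0.789, 0.739 and 0.691 in the same order. Nitrate and H2O2 in wild type, which share the mock libraries, raised 179 genes in common against 103 from independent lists and lowered 103 against 39.7, while 64 rose with nitrate and fell with H2O2 against 67.0, and 88 fell with nitrate and rose with H2O2 against 61.0. Simulated unchanged groups shared 0 calls, which follows from their lack of any true change, since almost no gene is then called. The covariance of these 2 responses across genes was 0.520 against a simulated 0.0711 from the shared controls, with r of 0.203 against 0.499. The observed genes all passed 2-fold with H2O2 and the simulated values were not so picked. The simulation therefore does not measure what shared controls add to 2 real responses. The hbi-q and nlp7-1 responses share no libraries with H2O2 against mock by the labels, and there 110 genes rose in common against 109.5 and 109 against 92.6, 92 fell in common against 43.4 and 79 against 46.1, and 199 fell with nitrate and rose with H2O2 against 66.7 and 160 against 68.0, with covariances of -0.0396 and 0.107. KNO3 with H2O2 was compared against the H2O2 libraries, so its calls share them with H2O2 against mock. Of those, 215 genes rose with H2O2 and fell when nitrate was added to it against 46.1, and 99 did the reverse against 45.0, with a covariance of -1.02 against a simulated -0.0732 and r of -0.467 against -0.499. The limit of the simulation holds for both pairs with shared libraries. The 3 controls allow no split, so part of each excess in these 2 pairs may come from them.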

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

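All tests of explanations in this part were chosen after the results were seen. The nitrate response differed from that of wild type in 1288 genes in hbi-q, 2552 in nlp7-1 and 5509 with H2O2, each by a test of the difference itself. With that test scaled by its robust SD, the counts were 465, 72 and 644. Of the genes named by rule, 44 of 59, 52 of 70 and 71 of 80 met the unscaled test. Those listed next also passed the threshold in opposite directions in the 2 responses compared.

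In hbi-q against wild type, AT1G26390 differed by -5.10 and AT1G26410 by -5.03, and both rose with nitrate in wild type and fell in hbi-q. AT1G26390 did the same in nlp7-1, with a difference of -4.19. With H2O2 the nitrate response of AT1G26390 differed by -6.67, that of AT3G60270 by -5.26 and that of AT3G03670 by -4.98. Upward differences with H2O2 were 8.06 for MRN1, 8.01 for LCR85, 5.16 for AT1G14960 and 2.94 for NRT2.4, all of which fell with nitrate alone and rose with nitrate added to H2O2. H2O2 alone had already moved several of these genes, so the 2 responses started from different levels. With it MRN1 stood at -3.07 ± 0.34 and NRT2.4 was lower too. Levels derived from base means and fold changes went from 1054 in mock to 163 with H2O2 for AT1G14960, and from 11.7 to 314 for AT1G26390. Over all genes, opposite calls were made for 14 genes in hbi-q, 6 in nlp7-1 and 62 with H2O2.

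Genes that differed from wild type overlapped between each pair of settings, and lower responses were shared by 372 genes between hbi-q and nlp7-1 against 58.3 from independent lists, by 535 between hbi-q and H2O2 against 107, and by 902 between nlp7-1 and H2O2 against 219. All 3 tests used the same wild-type response, whose chance values could make differences alike, but against that as the whole cause for hbi-q with nlp7-1 and for nlp7-1 with H2O2 stand covariances 5.16 and 8.36 times the highest simulated, 2.12 and 2.18 times with errors raised by the robust SD of the tests, and r of 0.535 and 0.508 against simulated 0.346 and 0.329. For hbi-q and H2O2 the ratios were 3.86 and 1.4 and r was 0.481 against 0.485, so there chance values cannot be told apart from a real overlap while the size of the errors is open. A real state of the wild-type mock libraries, such as low defence transcripts in those seedlings, is a second explanation, under which genes with a lower response in hbi-q would stand higher in hbi-q mock. Over the 244 such genes whose levels could be derived with the H2O2 table, of 800, the median implied log2 ratio of hbi-q to wild type was 0.479 in mock (interquartile range 0.242 to 0.885) and -0.379 after KNO3 (-0.649 to -0.0829), against -0.0538 and -0.127 for genes that did not differ. Picking genes for a lower response pushes both ratios this way, so this state and an effect of the mutations or of H2O2, which was not tested, cannot be told apart here.

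Shoot photosynthesis markers responded less to nitrate in nlp7-1 and with H2O2, with median differences of -0.89 and -1.09, and ribosomal protein genes moved with them (-0.54 and -0.18), though with robust scaling 0 shoot markers differed in nlp7-1 and 9 with H2O2. A smaller share of shoot tissue in the nitrate samples, or a larger one in their controls, could lower all markers by about the same amount. The SD of the differences over markers was 1.2 times their median standard error with H2O2 and 1.51 times in nlp7-1, where they ranged from -1.81 to 0.28. Root markers had a median difference of 0.37 with H2O2, the way a smaller shoot share predicts, with 4 higher (list test, adjusted p = 0.563) and 2 lower. H2O2 alone had lowered 11 of 21 root markers, so the control of that response already had a lower level. In nlp7-1 the median difference was -0.31, the opposite way, with 0 higher and 2 lower. How far root markers should rise depends on the unknown share of root RNA. Tissue share and a regulated change of these genes cannot be told apart from these tables, and the biological explanation was not tested.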

How the results depend on the processing

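The threshold settings were planned before the data were examined, and centring, robust scaling and picking on another table were added after. No paired analysis was possible because the tables hold no values per library, although groups share replicate numbers. For the same reason other normalizations (RLE, upper quartile), count filters, another tool, 1 fit of all libraries, leaving out each replicate, pseudocounts, set tests with a correlation, other splits of the samples and outlier tests were not run, and neither were the 5 comparisons of genotypes or of H2O2 at fixed nitrate. The H2O2 table holds only genes past 2-fold, so no lower fold limit, no fold limit and no filter on low means were tried there. No named gene changed direction, but the settings tried do not test direction. Limits on fold and adjusted p-value, the filter on low means and robust scaling leave the sign of every value as it was. Centring shifts differences only by the medians of the nitrate tables, which lay between -0.0073 and 0.0046. With it 208 of 209 differences of named genes kept their call.

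Without a fold limit, calls were 13369 for wild type, 13382 for hbi-q, 9641 for nlp7-1 and 11879 for KNO3 with H2O2, and at 1.5-fold 7107, 7466, 7213 and 5840. At 4-fold they were 751, 807, 745 and 352, and 598 for H2O2 alone. For differences of the nitrate response, in the order hbi-q, nlp7-1 and H2O2, calls with at least 2-fold were 273, 790 and 1206, with at least 4-fold 53, 112 and 290, with 1.5-fold 690 for hbi-q and 2723 for H2O2, and at an adjusted p-value under 0.01 they were 785 for hbi-q and 972 for nlp7-1. Scaling the test by its robust SD left 465, 72 and 644, and the cause was not tested, since standard errors too small for such a difference and broad real differences would lower the counts alike. Shared same-direction calls with no fold limit were 10960 for wild type and hbi-q, 7397 for wild type and nlp7-1, 8616 for nitrate without and with H2O2, 8028 for hbi-q and nlp7-1, 9468 for hbi-q and KNO3 with H2O2, and 6902 for nlp7-1 and KNO3 with H2O2. Of the list tests of differences 11 passed with at least 2-fold and 12 with robust scaling, against 20, and of the 6, 5 and 9 that passed, 2, 2 and 6 did so with at least 2-fold and 4, 0 and 6 with robust scaling. Newly passing with H2O2 were higher glutathione transferases with at least 2-fold (adjusted p = 0.0267), and lower glutathione transferases (0.0238) and lower salicylate and defence genes (0.0132) with robust scaling, so the glutathione transferases had no settled direction. The smaller counts at stricter fold limits follow from fewer genes passing each limit.

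Picking nitrate-responsive genes on a table outside the difference left 56 raised and 48 lowered genes with a weaker response in hbi-q and 136 lowered genes in nlp7-1. In hbi-q stronger responses then outnumbered weaker ones, and the cause was not tested. Picking on wild type pulls toward weaker responses. Picking on nlp7-1 may pull toward stronger ones, since its response correlated more with hbi-q than with wild type. An adjusted p-value under 0.01 in pairwise comparisons, leaving out the genes with the lowest base means, and centring on the median kept counts within 1.5 times. Of 541 values of named genes 46 lost their call at an adjusted p-value under 0.01 and 223 at 4-fold. Of the 209 that are differences of responses, 107 lost their call with robust scaling and 58 with at least 2-fold. Depth per library is unknown, and the larger standard errors of nlp7-1 limit it most.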

Other observations

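The gene lists and tests in this part were chosen after the data were examined. Of 7 genes of CC-type glutaredoxins, small redox proteins, 7 rose with nitrate in all 4 nitrate comparisons. Their median log2 fold changes in the authors' deposited tables were 6.77 in wild type, 7.15 in hbi-q, 6.10 in nlp7-1 and 6.68 with H2O2, and none of these 7 was listed for H2O2 alone. They are not all glutaredoxin genes. GRX480, outside this list, was listed as higher with H2O2, and its levels derived from base mean and fold change were 418 in mock and 1626 with H2O2. Anthocyanin genes went the other way, with 12 of 12 lower in wild type, 11 in hbi-q, 11 in nlp7-1 and 10 with H2O2, at medians of -2.18, -1.71, -1.90 and -1.58 in the authors' deposited tables. The anthocyanin regulator MYB90 fell by 4.64 ± 0.10 on the log2 scale in wild type in the authors' deposited table.

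Genes of indolic defence metabolism and FAD-linked oxidases rose with nitrate in 6 of 8 in wild type, and 4 fell and 1 rose in hbi-q, 1 fell and 1 rose in nlp7-1, and 5 fell when nitrate was added to H2O2, while H2O2 alone raised 6, in the authors' deposited tables. For CYP71A12, a P450 enzyme of camalexin synthesis, the nitrate response differed by -3.95 ± 0.15 between hbi-q and wild type (adjusted p = 8.86e-150). Genes of the marneral and thalianol clusters, which make root triterpenes, were lower with H2O2 in 7 of 7, at a median of -1.99 in the authors' deposited table, and 4 of 7 fell with nitrate in wild type. Root markers fell with H2O2 too, in 11 of 21 (adjusted p = 1.31e-10).

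Seed storage genes were lower with nitrate in hbi-q in 6 of 10, with CRU3 at -8.39 ± 2.45, SESA5 at -8.06 ± 2.43 and PAP85 at -7.01 ± 2.2 in the authors' deposited table, and none of 10 was called in wild type. Wild-type values lay below 0 too, from -1.29 to -0.51 with a median of -0.93. These genes did not pass the test of the difference between hbi-q and wild type, so a genotype difference is not shown. Their standard errors were a median of 9.16 times those of genes with a like base mean, so libraries within a group differed widely. Uneven seed or seed coat material between libraries is consistent with that, and no biological explanation was tested.

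One hypothesis was that untreated hbi-q seedlings differ from untreated wild type in the genes that H2O2 changes. Levels of each group were derived from the base means and fold changes of 2 separately normalized tables, on the assumption that the wild-type and hbi-q fit held 12 libraries and that the median gene listed for H2O2 did not differ. Across 1138 genes the covariance of the H2O2 response with the implied log2 ratio of hbi-q mock to wild-type mock was 0.262, against at most 0.0436 in 100 simulations with equal mock levels, and r was 0.236 across genes. The scale set the median of these 1138 genes to 0, so only the gap between raised and lowered genes can be read. That gap was small: 378 of 692 genes raised by H2O2 stood higher in hbi-q mock, at a median of 0.0484, and 255 of 446 lowered genes stood lower, at a median of -0.0708. Single genes were far larger, with implied log2 ratios of 4.73 for CYP71A12, 4.72 for AT1G26390 and 4.46 for AT1G26410. In the nlp7-1 results these 3 genes had base means of 1025, 326 and 62.5, with nitrate responses of -0.15, -1.23 and -0.31. Levels derived for wild-type mock were 11.7 for AT1G26390 and 8.10 for AT1G26410. Higher mock levels of these genes may therefore not be particular to hbi-q. These levels come from separately normalized tables and were not tested. The state of the wild-type mock seedlings and stress or defence signalling in untreated hbi-q both stay open as candidates.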
